A study of Danio rerio with 14 samples.

How the data were processed

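Pineal glands of adult Tg(aanat2:EGFP) zebrafish, in which green fluorescent protein marks the gland, were collected at 4-h intervals and their RNA was hybridised to Affymetrix zebrafish expression arrays. The fish lived under a cycle of 12 h of light and 12 h of darkness (LD) at 28 °C or were kept in constant darkness (DD) during the cycle of collection. Zeitgeber time (ZT) counts hours from lights on. Each condition had 7 arrays, at ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22 and a further collection called ZT2b, which the labels do not explain and which was used here as ZT2. Each array held RNA of 12 pooled glands of males and females. Per the labels' protocols, RNA went through 2 rounds of in vitro transcription, with an amplification of about 1800-fold. A condition therefore had a single pool at most times, and p-values measure the spread of pools around the fitted model. No date or batch was given in the sources used here, so a batch that separated LD from DD arrays and the light condition cannot be told apart.

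The deposited values are intensities, the MAS5 signal of each probe set on a linear scale. Per the submitters' processing notes, GCOS and MAS5 were used, and their versions were not given in the sources used here. The authors' scaling was recovered from the values: the mean after leaving out 2% of the probe sets at each end was 150.04 on 13 of the 14 arrays and 150.05 on the LD array of ZT6. The table held 15617 probe sets, of which 115 were controls. Detection calls were not used here. 1 cell was empty and its probe set was left out. No column of another series was found (0 columns).

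Of the 15502 probe sets that were not controls, 10795 had 1 gene symbol in the platform annotation, 135 had several and 4572 had none, which gave 8793 genes. Symbols were checked through the Entrez gene ID for 10711 probe sets, which changed 1 symbol, and 84 probe sets kept the platform's symbol. A probe set with several symbols or none was tested but not named. No genome build was named with the values, so no coordinates are given.

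Signals were transformed as log2(signal + 14.9), where 14.9 is the 25th percentile of all values, and no further normalisation was applied. A fold change on this scale understates the change of dim probe sets. Probe sets with a mean signal over the 14 arrays above 29.179, the 40th percentile of these means, were tested, which left 9299 probe sets and 6116 genes. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. Every adjusted p of a probe set below comes from limma. The 24-h rhythm was tested with cosine and sine terms of a 24-h period and the light condition as a term. Its size is the fitted distance from trough to peak on the log2 scale. This size cannot be below 0, so noise alone gives a value above 0. Rhythms in LD, in DD and their difference came from a model with cosine and sine terms for each condition. LD was compared with DD with the time of collection as a block over 6 times, since both conditions were collected at the same times. The same block was kept in separate contrasts for the day (ZT2, ZT2b, ZT6 and ZT10, with lights on in LD and off in DD), the night (ZT14, ZT18 and ZT22, dark in both) and the difference between the day and night contrasts. ZT2b was compared with ZT2 with light condition and collection in the model. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 under Python 3.11.15.

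Lists of genes, 24 in all, covered melatonin synthesis, the positive and negative limbs of the clock, PAR bZIP and E4BP4 factors, light-induced and DNA repair genes, immediate early genes, phototransduction, pineal and photoreceptor transcription factors, cholesterol synthesis, heat shock and cold-inducible genes, cell cycle, the mitochondrial respiratory chain, ribosomal proteins, and markers of glia, myelin, neurons, habenula, blood, vessels, leukocytes, skin, connective tissue with meninges, pigment cells and muscle. The ribosomal list was defined by a pattern of symbols and also took in the kinase genes rps6kal, rps6ka3a and rps6kb1b, and rps19bp1. The respiratory chain list, also defined by a pattern, took in genes of assembly factors, such as ndufaf1 and sdhaf2, and of inhibitors, atp5if1a and atp5if1b. The list of pineal transcription factors also held asip2b, a gene of the agouti family. A gene was represented by its probe set with the highest mean, and 606 genes had several. For rhythms, a list's share of rhythmic genes was compared with that of all other genes by a two-sided Fisher's exact test, adjusted over the lists. For LD against DD and its day, night and interaction contrasts, camera with a preset correlation of 0.01 tested whether a list's members ranked higher or lower than other genes, and the p with an estimated correlation was computed beside it. No list call in these 4 contrasts held with an estimated correlation. Fisher's exact tests treat genes as independent, so their p-values can be too small where members of a list vary together. The median, the mean and the test differed in sign for 7 lists in LD against DD, 5 by day, 2 by night and 7 in the interaction, none of them past the threshold.

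The models, filter, pseudocount, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest rhythm, the 5 largest rises and 5 largest falls among called genes in each contrast of LD with DD, a fixed set of pineal and clock genes (aanat2, asmt, tph1a, exorh, crx, otx5, per1b, per2, per3, cry1a, clocka, bmal1a, nr1d1, nr1d2b and fosab), and up to 4 called members of each list by smallest p, or up to 2 members given as values where none was called. It took only probe sets with 1 symbol. For asmt, per1b and nr1d1 no probe set was found by annotation, and per3 lay below the filter.

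Each model was tested on simulated data with 200 changed probe sets among 9299. Of changes of 1 on the log2 scale, 64% were recovered for the 24-h rhythm, 18% for the rhythm in LD, 19% for the rhythm in DD, 0% for the rhythm difference, 88% for LD against DD, 72% by day, 58% by night and 19% for the interaction. Of changes of 2, 98%, 87%, 83%, 39%, 99%, 94%, 98% and 84% were recovered. False calls made up 3.57% of calls for the 24-h rhythm, 9.48% for the rhythm in LD and 3.11% for LD against DD. The simulated noise was normal and independent between probe sets and arrays, with no array that stood apart and no batch. These shares therefore need not hold for the real arrays. The number of arrays limits the precision. Alternatives were a pseudocount of 1 or at the median of all values, no filter or a stricter one, quantile normalisation, median centring, other variance priors, 1 probe set per gene, another model of time, no block, leaving out ZT2b and leaving out each array in turn. Leaving out both ZT10 arrays, and testing lists without the DD array of ZT10, were added after the values were seen.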

Results

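Transcript levels in the pineal gland, a light-sensitive clock organ that makes melatonin at night, were measured over the day in adult zebrafish kept in a light-dark cycle (LD, 7 arrays) or in constant darkness (DD, 7 arrays). Each array held a pool of 12 glands. The median signal was 44.7 ± 2.57 in LD and 46.2 ± 2.34 in DD (SD, n = 7 each). Arrays correlated with the others of their condition with a mean r across probe sets of 0.944 to 0.951 in LD. In DD this was 0.951 to 0.958, apart from the DD array of ZT10, with 0.913. That array also had a geometric mean signal of 1713 for the poly-A spikes added before amplification, against 100.5 to 268.5 on the other 13, and a GAPDH 3'/5' ratio of 16.7, against 5.09 to 12.9.

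**Figure D1:**
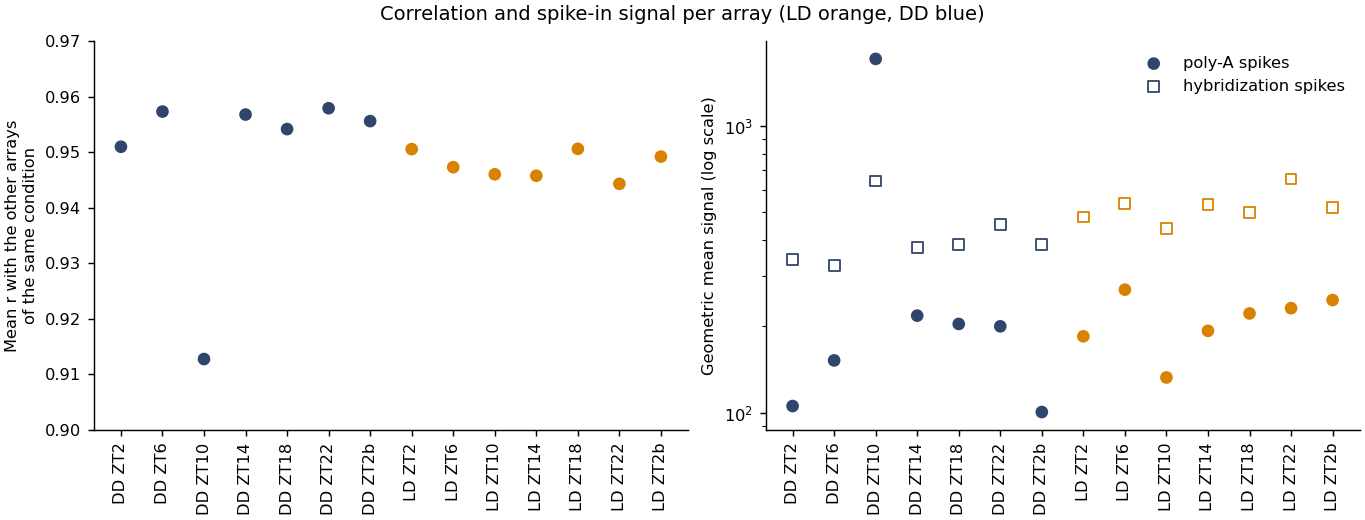
Left, mean correlation (r, across probe sets) of each array with the other arrays of its light condition; right, geometric mean signal of poly-A and hybridisation spikes per array on a log scale, LD in orange and DD in blue. The DD array of ZT10 has the lowest correlation, 0.913, and the highest poly-A signal, 1713.

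Which transcripts of the gland follow the time of day was asked over all 14 arrays. Clock genes had the largest rhythms. The signal of nfil3-5, a bZIP repressor of the E4BP4 family, rose from 47.6 at ZT2 to 6239 at ZT10 in LD and from 61.5 to 2513 at the same times in DD. Its fitted trough-to-peak change was 6.15 ± 0.53 (log2, SE), with a peak at ZT12.1 (adjusted p = 1.4e-05). The E-box repressors bhlhe41 and bhlhe40 changed by 5.22 ± 0.55 and 4.89 ± 0.61, with peaks at ZT0.667 and ZT3.95. ciarta, the fish relative of the repressor Chrono, changed by 4.72 ± 0.41 with a peak at ZT1.12. Among the 10 largest rhythms were also the nuclear receptor genes nr1d2b (3.46 ± 0.30, peak ZT2.13) and rorcb (3.19 ± 0.66, peak ZT10.1). The photoreceptor gene guca1c, whose protein regulates guanylate cyclase, changed by 3.31 ± 0.22 with a peak at ZT3.96 (adjusted p = 7.13e-07). The others were zgc:162144 (3.75 ± 0.37, peak ZT2.18), ndrg1b (3.68 ± 0.42, peak ZT14.6) and osbpl7 (3.1 ± 0.33, peak ZT3.47). Of these 10, rorcb alone lost its call with an array left out (adjusted p = 0.0203 with all arrays, 0.00282 to 0.345 over the alternatives). It had 0.0764 without the DD array of ZT10, 0.0979 without the LD array of ZT10 and 0.0686 without that of ZT22.

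In all, limma with Benjamini-Hochberg adjustment called 452 of 9299 probe sets rhythmic (300 genes). Of these, 312 changed by more than 1 on the log2 scale and 49 by more than 2. An unadjusted p under 0.05 was found for 1639, where chance gives 464.95. Peaks were most frequent after lights on and after lights off: 148 (32.7%) lay between ZT0 and ZT4 and 118 (26.1%) between ZT12 and ZT16. No test of this grouping was run. With ZT2b used as ZT2, that time had more arrays than others, which favours calls of waves with peaks near ZT2 or ZT14. The count was 260 without the ZT2b arrays, 282 without the LD array of ZT14 and 140 with an F-test over the 6 times of day in place of the 24-h wave. Without the DD array of ZT10 it was 571.

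**Figure D2:**
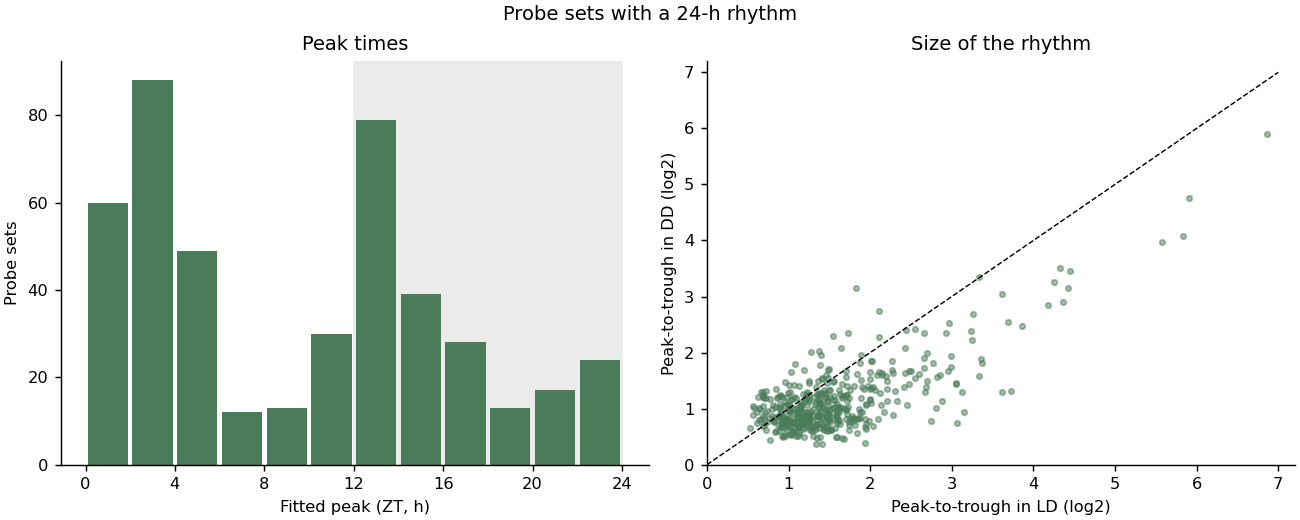
Left, fitted peak time (ZT, h) of the 452 rhythmic probe sets in 2-h bins, with the dark phase shaded; right, trough-to-peak change (log2) of each of them in DD against LD, with the line of equal size dashed. The median change is 1.39 in LD and 1.0 in DD.

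Shares of rhythmic genes in lists were tested as if genes were independent, so the p-values of Fisher's exact tests here and below can be too small. In the positive limb of the clock, 4 of 5 measured members were rhythmic (4 adjusted over the list alone, Fisher's exact test, adjusted p = 1.64e-04). bmal1a (2.54 ± 0.41), bmal1b (2.16 ± 0.31) and rorcb were highest between ZT10.1 and ZT11.8, and rorab (2.23 ± 0.35) at ZT6.52. In the negative limb it was 11 of 14 (13 adjusted over the list alone; Fisher's exact test, adjusted p = 2.54e-11). Of these, 8 had their peak between ZT0.667 and ZT5.23, and the other 3, among them the cryptochrome gene cry4 (2.42 ± 0.24), between ZT12.4 and ZT12.7. All 3 measured PAR bZIP and E4BP4 factors were rhythmic (3 adjusted over the list alone; Fisher's exact test, adjusted p = 5.61e-04). tefa (2.02 ± 0.23) peaked at ZT1.55 and nfil3-6 (2.37 ± 0.39) at ZT4.97. clocka, with 0.30 ± 0.33, was not called (adjusted p = 0.841).

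In melatonin synthesis, aanat2, whose enzyme sets the nightly rate of melatonin production in fish, changed by 2.33 ± 0.49 with a peak at ZT19.1 (adjusted p = 0.0240). Its signal was 3193 at ZT2 and 12482 at ZT22 in LD, and 2906 and 10143 at these times in DD. Its adjusted p ranged from 0.00547 to 0.0972 over the alternatives, and lay above the threshold without the DD array of ZT18 (0.0626) or of ZT22 (0.0583) or the LD array of ZT22 (0.0550). tph1a, the tryptophan hydroxylase of the pathway, had a fitted change of 1.38 ± 0.36 with a peak at ZT18.4 and was not called (adjusted p = 0.0810). With aanat2, 1 of 5 measured members was called, and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.485). The pineal photopigment gene exorh, at 9419 to 14442 on all arrays, and the homeobox genes crx and otx5 were not called (fitted changes 0.39, 0.49 and 0.23). Of 18 pineal transcription factors 0 were called (0 adjusted over the list alone).

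Genes of phototransduction were rhythmic in 13 of 31 cases (19 adjusted over the list alone; Fisher's exact test, adjusted p = 8.21e-09). The phosphodiesterase inhibitor subunit gene pde6hb (1.92 ± 0.21) and the retinoid-binding protein gene rbp3 (2.37 ± 0.29) were highest by day, at ZT6.16 and ZT5.85, and the cone transducin subunit gene gngt2b (2.25 ± 0.25) at ZT14.4. Heat shock and cold-inducible genes were rhythmic in 12 of 28 cases (15 adjusted over the list alone; Fisher's exact test, adjusted p = 1.87e-08). The chaperone genes hspa8b (1.96 ± 0.20) and hspd1 (1.30 ± 0.20) were highest at ZT4.19 and ZT4.23 and dnaja2b (0.98 ± 0.17) at ZT13.3. Of the light-induced and DNA repair genes, 5 of 17 were rhythmic (7 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00417). cry-dash (2.00 ± 0.30) and the damage-binding gene ddb2 (1.58 ± 0.31) were highest near ZT2 and the catalase gene cat (0.97 ± 0.15) at ZT13.1. ddb2 was at adjusted p = 0.0619 without the LD array of ZT14 (range 0.00428 to 0.0962). cry1a, a light-induced cryptochrome, changed by 1.90 ± 0.43 with a peak at ZT5.23 (adjusted p = 0.0344, 0.0182 to 0.264 over the alternatives). Its call was lost without the DD array of ZT2 (0.0558) or the LD arrays of ZT2 (0.0671), ZT6 (0.0600), ZT14 (0.0937), ZT18 (0.153) or ZT2b (0.0663).

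In the other lists few members were rhythmic and none of the Fisher's exact tests passed. These were immediate early genes (2 of 25, klf9 with 2.31 ± 0.32 and dusp6 with 0.81 ± 0.18), glia (2 of 11), and neurons, vessels and connective tissue (1 each, of 12, 4 and 18). dusp6 was not called without the DD array of ZT14 or ZT2b or the LD array of ZT14, ZT18 or ZT2b (adjusted p = 0.0545 to 0.130). Calls numbered 0 of the 17 cell cycle, 83 respiratory chain, 76 ribosomal and 10 cholesterol genes. Markers of myelin, habenula, blood, leukocytes, skin, pigment cells and muscle also had 0 calls, by limma over all probe sets. Adjusted over the list alone, the counts were 2 for immediate early genes, 3 for glia, 2 for vessels and 1 for pigment cells.

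**Figure D3:**
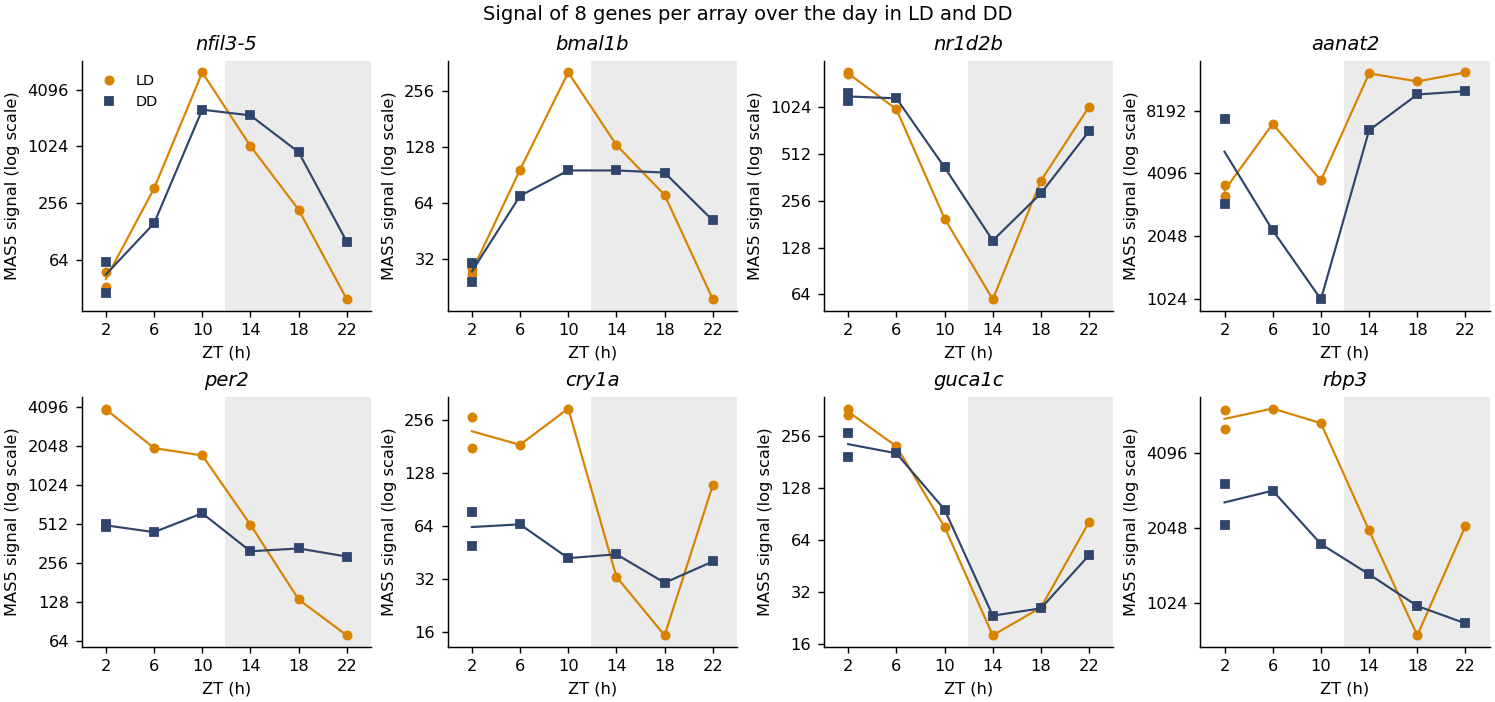
MAS5 signal (log scale) of 8 genes on each array against ZT (h), LD in orange and DD in blue, each point a pool of 12 glands, with the dark phase shaded. nfil3-5 peaks near ZT12 in both conditions, whereas per2 varies between 70.6 and 3974 in LD and between 286 and 618 in DD.

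To ask whether rhythms run without a light cycle, they were fitted in each condition. Collections covered a single cycle, apart from ZT2b, whose day is not given, so whether a fitted wave recurs could not be tested. In LD, 381 probe sets were rhythmic and in DD 60, and 52 were called in both, where 2.46 were expected of independent lists. Both fits share an estimate of the spread, so the lists are not independent, which can raise the overlap. Of the 381 called in LD, 318 (83.5%) had a fitted peak in DD within 4 h of that in LD. Among all 9299 probe sets tested the share was 45.0%, and 33.3% is the share at random times. Fitted peaks were later in DD, by a median of 0.69 h for the 452 probe sets rhythmic over both conditions. The median was 1.11 h for the 52 called in LD and DD and 0.83 h for all tested. No test of this shift was run. Some clock genes were called in both, 4 of 14 members of the negative limb and 1 of 5 of the positive limb in DD against 11 and 4 in LD. nfil3-5 changed by 6.86 ± 0.55 in LD and 5.90 ± 0.52 in DD, ciarta by 5.58 ± 0.51 and 3.97 ± 0.50, and nr1d2b by 4.18 ± 0.32 and 2.86 ± 0.32, with another of its probe sets peaking over 6 h away in DD. bhlhe41 changed by 5.91 ± 0.73 and 4.75 ± 0.71, and its call in DD was lost without the DD array of ZT14 (adjusted p = 0.0850), ZT18 (0.0517) or ZT2b (0.0937).

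Some genes had a large fitted rhythm in LD and a small value in DD. The median fitted size over all 9299 probe sets tested, most of them not called, was 0.44 in LD and 0.43 in DD. per2, a period gene induced by light, changed by 5.29 ± 0.86 in LD (peak ZT6.13, adjusted p = 0.00663), from 70.6 at ZT22 to 3974 at ZT2, and its value in DD was 0.90 ± 0.87 (adjusted p = 0.856). cry1a changed by 3.06 ± 0.49 in LD and had 0.74 ± 0.48 in DD (adjusted p = 0.730). Its call in LD was lost without the LD array of ZT18 (adjusted p = 0.0923). The cholesterol synthesis genes hmgcs1 (2.17 ± 0.44) and insig1 (1.69 ± 0.33) were called in LD, and neither was without the LD array of ZT2, ZT6, ZT14 or ZT2b (adjusted p = 0.0568 to 0.114 and 0.0635 to 0.0778). aanat2 had the larger value in DD, 3.15 ± 0.62 (adjusted p = 0.0702), against 1.82 ± 0.59 in LD (adjusted p = 0.207), and was called in neither condition alone.

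A difference between the rhythms was not called for any of these genes: limma called 0 probe sets in the test of the difference, with 662 at an unadjusted p under 0.05 and 464.95 expected. It called 2 with a robust variance prior and 2 with 1 probe set per gene. Values of the difference were 2.65 ± 0.37 for nfil3-6 (adjusted p = 0.0666, the smallest), 4.40 ± 1.22 for per2 (0.578), 2.33 ± 0.69 for cry1a (0.613) and 2.18 ± 0.84 for aanat2 (0.708). These values join differences in size and in peak time and have no direction, and aanat2 had the larger fitted rhythm in DD.

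In LD the lists past Fisher's exact test were those found over both conditions. Calls numbered 4 of 5 in the positive limb, 11 of 14 in the negative limb and 3 of 3 PAR bZIP and E4BP4 factors (4, 13 and 3 adjusted over the list alone). They numbered 7 of 17 light-induced, 12 of 31 phototransduction and 9 of 28 heat shock genes (9, 16 and 17 adjusted over the list alone). In DD these were the negative limb with 4 of 14 (Fisher's exact test, adjusted p = 2.91e-05), the PAR bZIP and E4BP4 factors with 2 of 3 (adjusted p = 0.00135) and phototransduction with 3 of 31 (adjusted p = 0.00706), guca1c, pde6hb and gngt2b (adjusted over the list alone 10, 3 and 16). Of these 3, only guca1c kept its call in DD with each array left out in turn, and pde6hb was at adjusted p = 0.313 without the DD array of ZT18 and gngt2b at 0.201 without that of ZT2. Of heat shock genes 1 of 28 was called in DD, hspa8b (adjusted p = 0.131 without the DD array of ZT14), and 13 adjusted over the list alone.

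Both counts depended on few arrays. The count in LD was 155 without the LD array of ZT14, 200 without that of ZT2b and 244 without that of ZT2. It was 156 without both ZT2b arrays and 598 without the DD array of ZT10, which enters through the shared estimate of the spread. The count in DD was 14, 17, 20, 20 and 32 without the DD arrays of ZT2b, ZT18, ZT2, ZT14 and ZT22. It was 29 and 35 without the LD arrays of ZT2b and ZT18, 13 without both ZT2b arrays and 103 without the DD array of ZT6.

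The effect of the light cycle on transcript levels, averaged over the day, was asked by setting LD against DD at the same times. The largest rise in LD was that of crtac1a, a gene of a secreted matrix protein, with a signal of 223.2 ± 92.0 in LD and 35.2 ± 14.7 in DD (SD, n = 7 each; 2.23 ± 0.26 on the log2 scale, adjusted p = 3.02e-04, limma). ptgdsb.2, of the prostaglandin D synthase family, had 552 ± 171 and 128 ± 75.5 (2.07 ± 0.18), and the zinc finger gene sall1a 449 ± 169 and 118 ± 29.9 (1.76 ± 0.20), each higher in LD in 7 of 7 collections. The largest fall was that of the adult globin gene hbba2, which fell by 3.25 ± 0.26 on the log2 scale (adjusted p = 4.67e-05). Its signal was 135 ± 42.5 in LD and 1523 ± 680 in DD, higher in LD in 0 of 7 collections. The phospholipase gene pla1a fell by 3.05 ± 0.57, the unnamed transcript wu:fb13g09 by 2.43 ± 0.49, the collagen chaperone gene serpinh1b by 2.28 ± 0.26 and igldcp by 2.21 ± 0.21. ddb2 rose by 1.40 ± 0.22. kng1 also rose, with 20 to 79.2 in LD, but 6 of its 7 values in DD, 4.5 to 8.4, lay below the pseudocount of 14.9, so the pseudocount sets the size of its change (0.85 to 2.55 over the pseudocounts tried).

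LD differed from DD in 1915 probe sets, 932 higher and 983 lower (606 and 627 genes), and 184 of these by more than 1 on the log2 scale. The balance depended on the scaling: 48.7% of the calls were higher in LD, against 54.1% after median centring and 51.8% after quantile normalisation. Among the fixed pineal genes, otx5, a homeobox gene of the pineal gland, rose by 1.09 ± 0.13 (232 ± 44.5 in LD and 101 ± 18 in DD; adjusted p = 3.47e-04), and cry1a by 1.03 ± 0.30 (adjusted p = 0.0295, with 0.0104 to 0.101 over the alternatives). The call of cry1a was lost with no block of collections (0.101) and without any of 9 single arrays, the DD arrays of ZT6, ZT10, ZT22 and ZT2b and the LD arrays of ZT2, ZT6, ZT10, ZT22 and ZT2b (0.0551 to 0.0693). aanat2 (0.58 ± 0.29), tph1a (0.20 ± 0.20, with another of its probe sets of opposite sign), exorh (0.15 ± 0.08), crx (0.12 ± 0.14) and per2 (1.01 ± 0.49) were not called. ddc, the decarboxylase of the melatonin pathway, fell by 0.51 ± 0.14 and was the only called member of the 5 measured (1 adjusted over the list alone). It was not called without either array of ZT6, ZT14 or ZT18 (adjusted p = 0.0542 to 0.0650). The count was 943 without both ZT2b arrays and 1267 of 6116 with 1 probe set per gene, and 2106 without the DD array of ZT10. The hybridisation spikes, added after amplification, had a geometric mean signal of 438 to 653 on LD arrays, and of 325 to 452 on DD arrays other than that of ZT10, with 643. No batch was named, so these differences and a batch of arrays cannot be told apart.

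Phototransduction genes were higher in LD as a list, with 10 of 31 members up and 2 down (11 and 2 adjusted over the list alone). The median was 0.25 and camera's adjusted p = 0.0106, against adjusted p = 0.586 with an estimated correlation. rcvrn3 (1.02 ± 0.12), rpe65a (0.74 ± 0.09; adjusted p = 0.0614 with no block) and pde6ha (0.90 ± 0.12), genes of recovery and the visual cycle, rose, and the red cone opsin gene opn1lw1 fell by 0.93 ± 0.16 (not called without the block, adjusted p = 0.113). Light-induced and DNA repair genes had 5 of 17 members up and 0 down (7 and 1 adjusted over the list alone). Their median was 0.36 and camera's adjusted p = 0.0262, against adjusted p = 0.586 with an estimated correlation. These included ddb2, cry-dash (1.01 ± 0.22) and tefa (0.83 ± 0.17), of which the latter 2 were not called with no block (adjusted p = 0.0988 and 0.151). Immediate early genes went the other way, with 0 of 25 up and 7 down (1 and 7 adjusted over the list alone), among them dusp6, which fell by 0.64 ± 0.13. Their median was -0.36 and camera's adjusted p = 0.0379, against adjusted p = 0.588 with an estimated correlation.

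Markers of other cells also differed. Of the leukocyte markers 0 of 18 were higher and 8 lower in LD (0 and 11 adjusted over the list alone). They had a median of -0.53 and camera's adjusted p = 0.00338 (adjusted p = 0.647 with an estimated correlation). Between the ZT2b and ZT2 collections, within conditions, the median of these markers was -0.69. marco, cxcr4b and ptprc fell by 1.06 ± 0.22, 0.92 ± 0.18 and 0.86 ± 0.19. Of the blood markers 1 of 12 was higher and 6 lower (1 and 7 adjusted over the list alone). These had a median of -0.53 and adjusted p = 0.0261 (adjusted p = 0.632 with an estimated correlation). Beside hbba2, the red cell anion exchanger gene slc4a1a fell by 1.03 ± 0.19 and the haem synthesis gene alas2 by 0.69 ± 0.17, while urod, of the same pathway, rose by 0.47 ± 0.13. Neuronal markers had 3 of 12 members higher and 0 lower (3 and 0 adjusted over the list alone). Their median was 0.30 and adjusted p = 0.0262 (adjusted p = 0.586 with an estimated correlation). The synaptic gene snap25a rose by 0.82 ± 0.21.

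**Figure D4:**
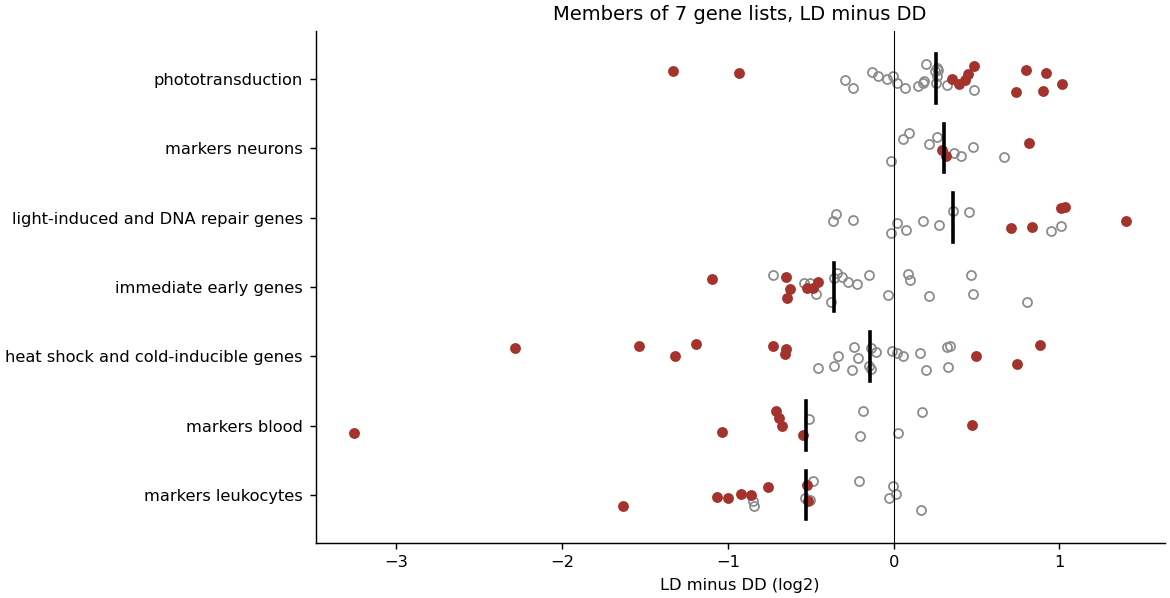
LD minus DD (log2) of each measured member of 7 gene lists, a point per gene, filled where limma called it, with the median of the list as a bar. Medians are 0.25 for phototransduction and -0.53 for both leukocyte and blood markers.

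The remaining lists did not pass camera's test. Heat shock and cold-inducible genes had 3 of 28 up and 7 down (3 and 10 adjusted over the list alone; adjusted p = 0.101). hspa8b and hsp70.3 fell by 1.19 ± 0.12 and 1.32 ± 0.16, and the cold-inducible gene cirbpb rose by 0.88 ± 0.11. Pineal transcription factors had 5 of 18 up, among them tbx2b (0.64) and noto (0.57). The negative limb had 4 of 14 up, among them fbxl3a (0.93 ± 0.11) and cry2 (1.2 ± 0.28; adjusted p = 0.0739 with no block). Each list was at adjusted p = 0.0704. Both passed without the DD array of ZT10, at 0.0351 and 0.0363, and with no filter on low values, each at 0.00545, where heat shock genes were at 0.0489. The respiratory chain had 14 of 83 up and 3 down and the ribosomal list 5 of 76 up and 7 down. Glial markers had 2 of 11 up and 2 down, s100b falling by 1.14 ± 0.14 and slc1a2b rising by 0.69 ± 0.13. The habenula marker kctd12.1 fell by 1.36 ± 0.14, 1 of 3 measured. In the cell cycle list 2 of 17 rose and 3 fell, and in the positive limb 1 of 5 and of the PAR bZIP and E4BP4 factors 1 of 3 rose. Connective tissue markers had 2 of 18 up, ptgdsb.2 and ptgdsb.1 (1.03 ± 0.16), and 2 down, of which cxcl12b fell by 1.35 ± 0.23. Skin markers had 2 of 21 up, pigment cells 1 up and 1 down of 2, myelin and vessels 1 down each, and cholesterol synthesis and muscle 0 calls by limma over all probe sets. Adjusted over the list alone, the counts up and down were 6 and 1 for pineal transcription factors, 15 and 3 for the respiratory chain, 3 and 5 for ribosomal genes, 2 and 4 for the cell cycle, 0 and 2 for myelin, and 0 for skin, cholesterol synthesis and muscle. In the other lists of this paragraph they were those over all genes.

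Whether light at the time of collection matters was asked by setting LD against DD by day, when lights were on in LD only. per2 rose by 2.36 ± 0.34, with 2882 ± 1200 in LD and 514 ± 74.9 in DD (SD, n = 4 each; adjusted p = 0.00331, limma), and cry1a by 1.74 ± 0.28. The largest rises beside per2 were those of crtac1a (2.44 ± 0.35), ptgdsb.2 (1.99 ± 0.25), the kinase gene plk3 (1.84 ± 0.23) and bokb of the BCL2 family (1.81 ± 0.20). hbba2 fell by 3.06 ± 0.34, and the salt-inducible kinase gene sik1 fell by 2.70 ± 0.25 (575 ± 298 in LD and 3573 ± 832 in DD). Next were igldcp, which fell by 2.37 ± 0.29, the clotting factor gene f13a1a.1, which fell by 2.14 ± 0.21, and the blue cone opsin gene opn1sw2, which fell by 2.04 ± 0.35 (adjusted p = 0.0698 without both ZT2b arrays). otx5 rose by 1.31 ± 0.15.

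By day 858 probe sets differed, 462 higher and 396 lower in LD. Light-induced and DNA repair genes were higher as a list, with 5 of 17 members up, among them ddb2 (1.78 ± 0.25) and cpdp (1.18 ± 0.18), and 0 down (7 and 1 adjusted over the list alone; camera's adjusted p = 0.00357). This was adjusted p = 0.283 with an estimated correlation. Blood markers were lower, with 0 of 12 up and 2 down (1 and 6 adjusted over the list alone; adjusted p = 0.0379), which was adjusted p = 0.669 with an estimated correlation and, with the preset one, 0.0817 without the DD array of ZT10. Immediate early genes did not pass as a list (median -0.21, camera's adjusted p = 0.313), with 1 of 25 higher, jun, which rose by 1.51 ± 0.22, and 4 lower (1 and 4 adjusted over the list alone). Of the latter, cremb fell by 1.61 ± 0.38, dusp6 by 0.72 ± 0.18 and dusp5 by 0.69 ± 0.15, and nr4a1, named after its values were seen, fell by 0.68 ± 0.18. cremb was not called without the DD array of ZT6, ZT10 or ZT2b or the LD array of ZT2, ZT6 or ZT10 (adjusted p = 0.0566 to 0.0798). dusp6 was not without the DD array of ZT2, ZT6 or ZT2b or the LD array of ZT6 or ZT2b (0.0553 to 0.0923), nor dusp5 without the DD or LD array of ZT2b (0.0581 and 0.0546). The count was 83 without both ZT2b arrays, 325 and 355 without the DD or the LD array of ZT2b, 533 without the LD array of ZT2, and 519 and 517 without the DD or the LD array of ZT6.

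By night, when both conditions were dark, ptgdsb.2 (2.18 ± 0.28), crtac1a (1.95 ± 0.40), sall1a (1.79 ± 0.31), the parvalbumin gene pvalb8 and kng1 had the largest rises in LD on the scale used. The last 2 had signals below the pseudocount of 14.9, which sets their size and rank: pvalb8 had 3.1 in DD and 3.8 in LD at ZT22, and kng1 had 4.5 and 8.4 in DD at ZT14 and ZT22 and 40.7 at ZT18. Neither was called with a pseudocount of 1 (adjusted p = 0.111 and 0.0534, with 0.0293 to 0.285 and 0.0197 to 0.233 over the alternatives). pla1a fell by 4.04 ± 0.84, hbba2 by 3.51 ± 0.40, serpinh1b by 2.79 ± 0.36, the interferon regulator gene irf7 by 2.28 ± 0.47 and the small heat shock gene hspb1 by 2.26 ± 0.41. The clock genes rorcb, whose LD mean of 14 ± 10.9 (SD, n = 3) lay below the pseudocount too, and nfil3-5 fell by 1.90 ± 0.35 and 1.52 ± 0.32, and with no block of collections these and pvalb8 were not called (adjusted p = 0.268, 0.703 and 0.232). For rhythmic genes such as rorcb and nfil3-5 a contrast of one phase joins differences in level and in peak time, which were not separated. otx5 rose by 0.79 ± 0.17 (adjusted p = 0.0383, limma), and per2, with -0.79 ± 0.39, was not called. In all, 272 probe sets differed, 127 higher and 145 lower, and 164 against 105 with each array centred on its median. After quantile normalisation 52.9% of the night calls were higher in LD, against 46.7% here.

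At night 8 lists passed camera's test. Phototransduction was higher (5 of 31 up and 0 down, 9 and 1 adjusted over the list alone; adjusted p = 4.04e-05), as were neuronal markers (0 of 12 called, 2 up adjusted over the list alone; adjusted p = 0.00468) and pineal transcription factors (1 of 18 up, 4 adjusted over the list alone; adjusted p = 0.0320, and 0.0543 after quantile normalisation). Each was at adjusted p = 0.230 with an estimated correlation. Leukocyte markers were lower (0 of 18 called, 11 down adjusted over the list alone; adjusted p = 4.04e-05), as were blood markers (1 of 12 down, 4 adjusted over the list alone; adjusted p = 0.0409). Each was at adjusted p = 0.561 with an estimated correlation, and blood was at 0.0813 without the DD array of ZT10 with the preset one. Immediate early genes (0 of 25 called, 0 adjusted over the list alone, limma; adjusted p = 0.00356) and heat shock genes (1 of 28 up and 5 down, 1 and 7 adjusted over the list alone; adjusted p = 0.0320) were lower. Each was at adjusted p = 0.440 with an estimated correlation. The habenula list (1 of 3 down, 1 adjusted over the list alone; adjusted p = 0.0176) was at adjusted p = 0.245 with an estimated correlation.

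The night count rests on 3 collections. It was 0 without either array of ZT18, so that no gene named for the night kept its call there. It was 5 without either array of ZT22 and 26 without either of ZT14. Without the DD or LD array of ZT2b it was 143 or 145, without the LD array of ZT2 155, without both ZT2b arrays 15 and with no filter 138. Without the DD or LD array of ZT10 it was 599 or 602, through the shared estimate of the spread.

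Of the probe sets called by day and by night, 152 were called in both, all with the same sign, where 12.5 with the same sign were expected of independent lists. Both contrasts share an estimate of the spread, so the lists are not independent, which can raise the overlap. Of the day calls 793 (92.4%) had the same sign at night. The difference between day and night was itself called for 0 probe sets by limma, with 527 at an unadjusted p under 0.05, where 464.95 are expected, and 1 call at most with an array left out (without either array of ZT14 or the LD array of ZT2). Its largest values among named genes were those of per2 (3.16 ± 0.52, adjusted p = 0.152), rorcb (2.58 ± 0.47, 0.176), nfil3-5 (2.1 ± 0.42, 0.267) and, downward, nr2e3 (-1.89 ± 0.43, 0.305). For rhythmic genes such values join differences in level, in the size of the rhythm and in peak time.

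For 5 lists, none with a called member, LD minus DD differed between day and night in camera's test with the preset correlation, and for 0 of 24 lists with an estimated one. The value was higher by day for the positive limb (0 of 5 called by limma, 3 up adjusted over the list alone; camera's adjusted p = 0.00240, and adjusted p = 0.177 with an estimated correlation). It was so too for light-induced genes (0 of 17, 3 up adjusted over the list alone; adjusted p = 0.00748, and adjusted p = 0.225 with an estimated correlation). The PAR bZIP and E4BP4 factors (0 of 3, 2 up adjusted over the list alone; adjusted p = 0.0331) were at adjusted p = 0.267 with an estimated correlation. Leukocyte markers (0 of 18, 0 adjusted over the list alone; adjusted p = 0.0331) were at adjusted p = 0.763 with an estimated correlation, and at 0.422 without the DD array of ZT10 with the preset one. Phototransduction (0 of 31, 0 adjusted over the list alone) was lower by day than by night, with adjusted p = 0.00748, and adjusted p = 0.339 with an estimated correlation and, with the preset one, 0.0613 after quantile normalisation. With no filter on low values 2 of these 5 lists passed, light-induced genes and leukocyte markers. In lists of rhythmic genes, such as the positive limb, these values too join differences in level and in peak time.

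**Figure D5:**
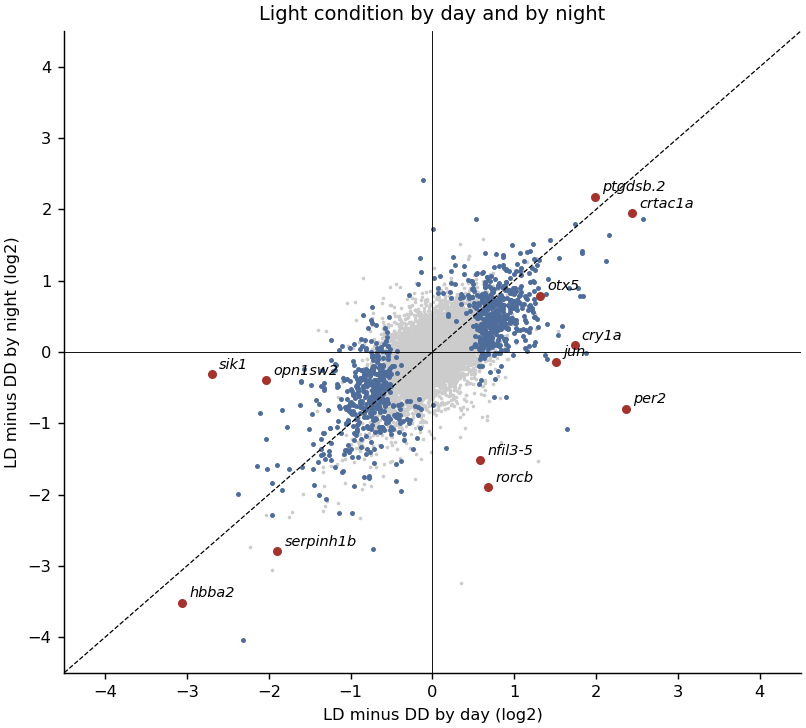
LD minus DD by night against LD minus DD by day (log2) for each of 9299 probe sets, with those called in either phase in colour. The values correlate with r = 0.64 across probe sets, and hbba2 lies at -3.06 by day and -3.51 by night.

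The ZT2b collections, which the labels do not explain and which were used as ZT2, were set against ZT2. They correlated with r = 0.969 in LD and 0.963 in DD across probe sets, and no probe set was called between them in limma (0 called, 221 at an unadjusted p under 0.05 and 464.95 expected). The comparison rests on few arrays and its power was not simulated, so a lack of calls does not show that the collections were alike. Leukocyte markers had a median of -0.69 in ZT2b minus ZT2, a larger size than the -0.53 of LD minus DD, with 0 of 18 called by limma and 4 lower adjusted over the list alone.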

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

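The tests of less RNA, of a state of the gland at ZT10, of light at collection, of red blood cells, of the DD array of ZT10 as a cause of fewer rhythms, of a smaller rhythm in DD and those with the mean of each condition removed were chosen only after the result was seen, and the other counts over splits of the arrays were planned.

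The DD array of ZT10 stood apart from the others: its mean r with the other DD arrays was 0.913, where these had 0.951 to 0.958, and its geometric mean poly-A spike signal was 1713, where the other DD arrays had 100.5 to 217.9. Poly-A spikes are added before amplification and hybridisation spikes after it, and their log2 ratio on this array was 2.72 above the mean of the other 13 (SD 0.35). Less pineal RNA in the amplified sample, a technical cause, is consistent with that value. A state of the gland at ZT10 in both conditions is argued against by the LD array of ZT10, whose mean r of 0.946 lay within the range of the other LD arrays, of which the lowest had 0.944. A state of the gland at ZT10 in DD alone stays open, since no other array was of that time and condition.

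LD against DD gave 1915 calls. With light labels exchanged within collections, 1 of 64 exchanges, the real one, gave as many, and the highest other gave 220. This argues against chance. Of 100 splits of the arrays into 7 and 7, 1, the real one, gave as many and the highest other gave 15. These splits were not kept within times, and unbalanced ones let the difference between LD and DD into the residual spread. That lowers their count, so they do not exclude chance. Light at the time of collection as the whole cause of the day differences is argued against, since the probe sets called by day had a median of 0.51 in the same direction at night, when both conditions were dark (0.79 by day, and 0.49, 0.47 and 0.61 in the 3 night collections). For hbba2, which fell by 3.25, more red blood cells in the DD pools as the whole cause is argued against by a median of -0.51 (SD 0.45) for the other 11 members of the blood list. Of these, hbaa1, highest in signal, had 8224 ± 1812 in LD and 11994 ± 2254 in DD. A smaller share of blood and leukocytes in the LD pools may account for part of the lower markers of these cells, and a variant of hbba2 in some fish was not tested. A batch of arrays and the light history of the fish cannot be told apart, since no batch was named for either condition, and the hybridisation spikes had 523 ± 66.7 on LD arrays and 378 ± 43.9 on DD arrays other than that of ZT10.

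More probe sets were rhythmic in LD (381) than in DD (60). For each count 1 of 100 random orders of the times, the real one, gave as many, with 134 and 51 the highest others. This argues against chance for the count in LD, while in DD the highest other lay close to the real count. These orders tested each count alone and not the difference between them. Without the DD array of ZT10, DD had 57 rhythmic probe sets and LD 598, so leaving it out did not close the gap. Whether that array lowered the count in DD cannot be told, since the loss of an array can itself lower it. The count in DD was 14 to 32 without the DD array of ZT2, ZT14, ZT18, ZT22 or ZT2b, and 103 without that of ZT6. A smaller rhythm in DD is consistent with the amplitudes of the 452 probe sets rhythmic over both conditions: the median over probe sets of the LD minus DD difference in amplitude was 0.42, where 1 of 64 exchanges of light labels within collections, the real one, gave as much (highest other 0.41, or 0.36 with the mean of each condition removed first, again 1 of 64). Without both ZT10 arrays 2 of 32 exchanges gave as much (0.47 for the real labels, highest other 0.49), and 1 of 32 with these means removed (highest other 0.44). The median residual SD was 0.24 in LD and 0.27 in DD, a batch in either condition stays open, and no probe set was called in limma's test of the difference, where 662 had an unadjusted p under 0.05 and 2 were called with a robust prior or 1 probe set per gene.

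For the 24-h rhythm over both conditions 1 of 100 random orders of the times gave 452 calls, the real one, and the highest other gave 123. This argues against chance if the arrays are independent, but the times were drawn separately within LD and within DD. A deviation shared by the arrays of a collection was thus not tested. LD and DD arrays of a collection had r of up to 0.32 (ZT2b) after the mean of each condition was removed. That r also holds any rhythm common to both conditions, so it does not measure such a deviation. By day the real split, 1 of 34, gave 858 calls and the highest other 6. This does not exclude chance, since the splits were not restricted to exchanges within times. In splits that were unbalanced over the times, the difference between LD and DD entered the residual spread and lowered the count. 1 of 35 splits could not be fitted. At night 10 splits are too few for a share under 0.05: the real split, 1 of 10, gave 272 and the highest other 4. Chance cannot be excluded for the difference between day and night, where 11 of 35 ways to call collections day gave as many probe sets at an unadjusted p under 0.05 (527 for the real one, highest other 808). For the difference of rhythms, 32 of 64 exchanges of light labels within collections gave at least the real 662, which decides nothing about chance. The highest, 2775, came from exchanging ZT10, ZT14 and ZT18 and points to a structure of the samples: the constant difference between LD and DD arrays then enters as a rhythm. With the mean of each condition removed first, chance cannot be excluded, with 25 of 64 exchanges at or above 662 and 1117 the highest other.

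Chance alone sets about 1 in 20 groups apart in this way: 2 of 10 array measures and 4 of 42 groups of values of named genes were past the limit of Dixon's test. crtac1a had 7.9 on the DD array of ZT10 and 29.7 to 54.0 on the other DD arrays. tph1a had 1732 on that array and 3680 to 6128 on the others. kng1 had 40.7 on the DD array of ZT18 and 4.5 to 8.4 on the others. wu:fb13g09 had 411.9 on the DD array of ZT2 and 1372 to 1877 on the others.

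Lists whose LD minus DD value differed between day and night in camera's test with the preset correlation, and in none with an estimated one, had these medians of day minus night on the log2 scale. The positive limb had 0.85, the PAR bZIP and E4BP4 factors 1.52, light-induced and DNA repair genes 0.42, phototransduction -0.16 and leukocyte markers 0.43, the last at adjusted p = 0.422 without the DD array of ZT10.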

How the results depend on the processing

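The alternatives without both ZT10 arrays, and gene lists without the DD array of ZT10, were chosen only after the values were seen. No called value of a named gene changed its sign, but the balance of higher and lower calls turned under other scalings. Most counts within 1.5 times of the main ones are not listed, and where no construction is named the cause was not tested.

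Fewer arrays lowered most counts. Without both ZT2b arrays the counts were 260 for the 24-h rhythm, 943 for LD against DD, 83 by day, 15 by night, 156 for the rhythm in LD and 13 for that in DD. Of the 452 rhythmic probe sets 255 were still called there, and of the 1915 that differed between LD and DD 926 were. Without both ZT10 arrays the counts were 601 by night and 573 for the rhythm in LD, above those with all arrays. By night these arrays enter only through the shared estimate of the spread. With 1 array left out the counts were 282 to 571 for the 24-h rhythm, 325 to 831 by day, 0 to 602 by night, 0 to 1 for the difference between day and night, 155 to 598 for the rhythm in LD, 14 to 103 for the rhythm in DD and 0 to 1 for the difference of rhythms. For LD against DD they were 1374 to 2106.

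An F-test over the 6 times of day called 140 for the 24-h rhythm. With 1 probe set per gene LD differed from DD in 1267, with fewer tested by construction, and the difference of rhythms was called for 2. A robust prior called 2 for that difference as well. No filter on low values gave 138 by night. After quantile normalisation 438 of the 452 rhythmic probe sets and 1814 of the 1915 LD against DD calls were shared, and after median centring 443 and 1817. For LD against DD the share higher in LD was 48.7% of the calls, 51.8% after quantile normalisation and 54.1% after centring. By night it was 46.7% (127 higher and 145 lower), 52.9% and 61.0% (164 and 105).

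With an estimated correlation 0 lists passed in LD against DD, by day, by night and in the difference between day and night, where the preset one gave 6, 2, 8 and 5. With no filter 5 lists passed by day and 2 in the difference between day and night. Without the DD array of ZT10 the lists past the threshold numbered 7 for the 24-h rhythm, 8 for LD against DD, 3 by day, 7 by night and 6 for the difference between day and night.

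With no block of collections the counts were 1669 for LD against DD, 765 by day, 239 by night and 0 for the difference between day and night. After the mean of each condition was removed, LD and DD arrays of a collection correlated with r from -0.018 (ZT6) to 0.32 (ZT2b) across probe sets. These deviations keep any rhythm common to both conditions. Of the 7 LD arrays, 2 correlated best with the DD array of their own collection. The LD array of ZT2 correlated best with the DD array of ZT2b, which shares its block. The block therefore rests on the design, not on this check.

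Of 13022 values of named genes under the alternatives, 12138 stayed on their side of the threshold, 776 lost a call and 108 gained one. The number of arrays, and a single pool per time and condition, limit the precision.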

Other observations

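The hypotheses and groupings here were chosen after the values were seen, and no test beyond those named was run.

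The 13 rhythmic genes of phototransduction over both conditions had 6 peaks by day and 7 by night, and no test of a grouping was run. By day these were rpe65a at ZT0.986 (1.30 ± 0.19, log2 and SE), guca1c at ZT3.96 (3.31 ± 0.22), rcvrn3 at ZT5.02 (0.96 ± 0.16), rbp3 at ZT5.85 (2.37 ± 0.29), pde6hb at ZT6.16 (1.92 ± 0.21) and pde6ha at ZT8.58 (0.99 ± 0.17). By night they were opn1lw1 at ZT12.1 (2.07 ± 0.25), guca1aa, of the same family as guca1c, at ZT17.5 (1.92 ± 0.39), and 5 genes of transducin beta and gamma subunits, which carry the signal from opsins. Of the latter, gnb1b peaked at ZT12.5 (1.45 ± 0.22), gnb1a at ZT14.0 (1.03 ± 0.19), gngt2b at ZT14.4 (2.25 ± 0.25), gnb3b at ZT15.1 (1.51 ± 0.25) and gngt2a at ZT16.4 (1.03 ± 0.16).

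Of the 12 rhythmic heat shock and cold-inducible genes 9 had their peak by day and 3 by night, again with no test of a grouping. serpinh1b, hsf2, hsp70.3, hspe1, hspa9, hspa8b, hspd1 and hsp90aa1.2 peaked between ZT1.70 and ZT4.66, and hsf1 at ZT9.64. By night, dnaja2b peaked at ZT13.3 (0.98 ± 0.17), cirbpb, a cold-inducible RNA-binding protein gene, at ZT15.9 (0.90 ± 0.16) and fkbp5 at ZT23.7 (1.88 ± 0.32). klf9, known like fkbp5 as a target of glucocorticoid signalling, peaked at ZT21.5 (2.31 ± 0.32). The vessel marker plvapb peaked at ZT20.2 (1.16 ± 0.22), and the water channel gene aqp1a.1, on the list of glia, at ZT1.41 (1.18 ± 0.16).

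Of the 452 rhythmic probe sets 153 also differed between LD and DD, where 93.1 were expected of independent lists. Both tests use the same arrays, so the lists are not independent, which can raise the overlap. In the comparison of ZT2b with ZT2, where limma called 0 probe sets and 221 had an unadjusted p under 0.05, leukocyte markers had a median of -0.69 (4 of 18 lower adjusted over the list alone), skin markers -0.52 (0 of 21) and neuronal markers -0.16 (3 of 12 lower).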
